A study of Mus musculus with 8 samples.

How the data were processed

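The measurements were Omni-ATAC-seq libraries of primary mouse LSECs, 4 from chow-fed and 4 from FFC-fed C57BL/6J mice that were 8 weeks old when a feeding period of 24 weeks began. Per the labels, livers were perfused with collagenase, hepatocytes were removed by slow centrifugation, and LSECs were taken from the remaining cells with CD146 magnetic beads. About 50000 cells went into each library, and libraries were read as 51 bp pairs. The labels do not expand FFC, and they do not say whether the libraries came from separate mice, so p-values measure the spread between these libraries, which may be in part technical.

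The deposited data were 1 list of peaks per library, called per library and not on pooled libraries. Per the submitters' processing notes the tools were BWA, Picard, MACS2 and bedtools and the build was mm10; versions, thresholds and the handling of the transposase offset are not given in the sources used here. Each row of a list has 5 columns, with the position, a peak name and a number. That number is the authors' score per peak, per the file headers with no scale named, and its lowest value in the deposited lists ran from 2.05 to 2.61. It was used only to rank peaks within a list. Of the 13 library measures 1 was the median score, with 9.76 ± 2.10 (SD, n = 4) in Chow and 12.4 ± 1.92 (SD, n = 4) in FFC (exact permutation p = 0.143, adjusted p = 0.26); no other comparison set scores of different libraries against each other. The lists hold no read totals, so depth per library is unknown and no interval that needs it is given. A longer list can come from deeper or cleaner sequencing as well as from more open chromatin. All lists carry the name of the same flow cell lane, so no sequencing batch could be separated. No peaks were removed for known artefact regions.

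Genes came from a RefSeq table of the GRCm38.p6 assembly, the build that mm10 is, which gives each gene's start and end without strand or exons. Promoters could therefore not be told from the far ends of genes, and a gene-end window, within 1 kb of either end of a protein-coding gene, took the place of the planned promoter window. Exons, introns and untranslated regions were not separated. No genome sequence was used here, so the planned motif and GC comparisons were not run. Of 405 list genes, 402 were matched, 2 of them by synonym; Mx1, Mx2 and Ighm were not. Neighbouring genes can share a peak: Eri2 lies end to end with Rexo5, and Arsg with Slc16a6, and both neighbours had the same counts of libraries.

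Peaks of all 8 lists were merged where they overlapped by at least 1 bp, and a library occupied a region if any of its peaks overlapped it. Library values were compared by exact permutation tests over all 70 assignments of 4 and 4 libraries, two-sided, where the smallest possible p is 0.0286. Overlap was tested one-sided over 35 splits. Regions and genes were compared by Fisher's exact test, and by an exact conditional test with 1 odds term per library, fitted by conditional maximum likelihood over all regions to take out list length. Gene lists were tested as log2 odds of a gene-end peak within each library, with 0.5 added to each cell, and as the percent of distal peaks within 10 kb of the list's genes. Benjamini-Hochberg adjustment was made within each family. With 24 lists, none can pass 0.05 after adjustment unless most of them reach the smallest p.

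The 24 lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took 16 genes in any case, list genes differing by 3 or 4 libraries (at most 20), up to 10 genes per direction with gene-end peaks in all libraries of one group and none of the other (those that keep this at equal length first, which was true of 0 genes, then by name), and up to 5 regions per direction by p of the conditional test. The alternatives were lists of equal length, the better part of each list, another overlap, other windows, autosomes only, a looser occupancy, each library left out in turn and pairing by replicate number. A further 3 were added after seeing the data: leaving out the shortest and the longest list, the 6 longest lists at equal length, and list occupancy relative to fitted library odds.

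The tests were tested on simulated data. For FFC against Chow over 24825 simulated regions with the library odds of the real lists, 1.93% of unchanged regions had an unadjusted p under 0.05 and 0 were called. Of 100 regions raised in Chow by an odds ratio of 50.0, 29 had an unadjusted p under 0.05 and 0 were called after adjustment. Of 100 raised in FFC, 0 reached an unadjusted p under 0.05. The simulated regions followed the model that the conditional test assumes, with libraries drawn independently. The region rates therefore do not cover departures of the real lists from that model. For lists of 20 genes among 21887 simulated genes, 2.6% of 960 unchanged lists had an unadjusted p under 0.05, as did 40 of 40 lists raised by 2.58 on the log2 odds scale. Within a library every unchanged simulated gene had the same chance of a peak. These rates therefore do not cover an effect of list length on lists of real genes. The simulated rise exceeded the largest observed list difference, 1.19, so power for the observed differences was not tested. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.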

Results

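Liver sinusoidal endothelial cells (LSECs) line the capillaries of the liver and are known for scavenger receptors, open pores and a low barrier to the blood. Open chromatin of these cells was profiled by Omni-ATAC-seq, in which a transposase inserts sequencing adapters where DNA is accessible. The series compared 4 libraries from chow-fed C57BL/6J mice (Chow) with 4 libraries from mice kept for 24 weeks on a diet labelled FFC, which the labels tie to non-alcoholic steatohepatitis (NASH). The question was where open chromatin of LSECs differs between NASH and control mice. The data were 1 list of peaks per library, with positions in mm10. Read depth per library was unknown from these lists, so the length of a list stood beside every comparison.

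FFC lists were on average longer than Chow lists, but the groups overlapped. The Chow lists held 2893, 7585, 12045 and 12419 peaks for replicates 1 to 4, and the FFC lists held 12586, 10143, 15431 and 23582. The means were 8735.5 ± 4471 (SD, n = 4) and 15435.5 ± 5845 (SD, n = 4), a ratio of 1.77. On the log2 scale the difference was 0.96, and it was not larger than the spread between libraries (exact permutation test, two-sided, p = 0.114 over 70 assignments, adjusted p = 0.26 over the 13 library measures). The difference was 0.49 without Chow replicate 1 and 0.27 without the shortest and the longest list. Peaks within 1 kb of an end of a protein-coding gene made up 64.8% ± 5.98 (SD, n = 4) of Chow peaks and 56.6% ± 9.46 (SD, n = 4) of FFC peaks (exact permutation p = 0.171, adjusted p = 0.26). The difference of -8.27 percentage points was -3.76 without FFC replicate 4 and -1.50 without the shortest and the longest list. With every list reduced to its best 2893 peaks by score, this direction turned, and the share was 4.45 percentage points higher in FFC (exact permutation p = 0.0286). That setting keeps the whole list of Chow replicate 1 and only the best-scored peaks of the longer lists, so it does not separate diet from list length. Intergenic peaks made up 15% ± 1.87 (SD, n = 4) in Chow and 18.9% ± 4.31 (SD, n = 4) in FFC (exact permutation p = 0.114, adjusted p = 0.26).

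**Figure D1:**
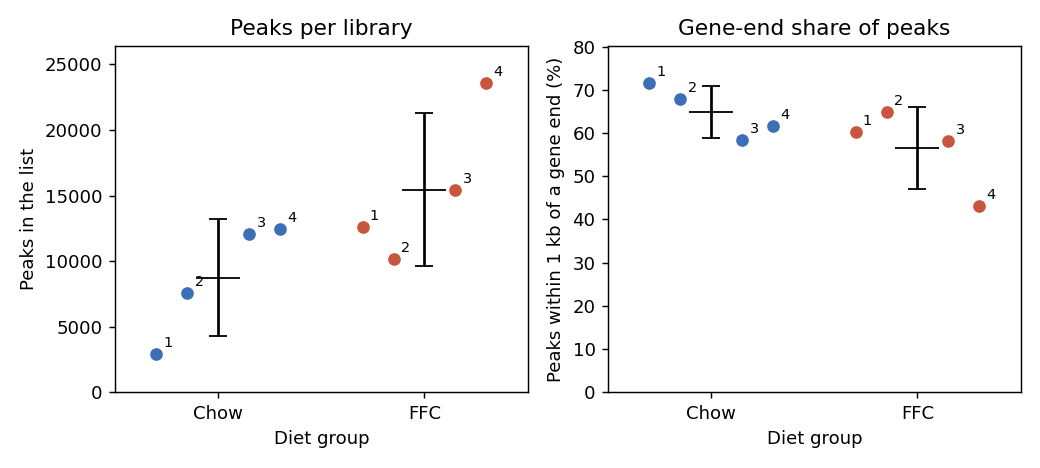
Number of peaks in each list (left) and percent of peaks within 1 kb of a gene end (right) for the 4 Chow and 4 FFC libraries; points are libraries with their replicate number, and the bars show the mean ± SD of each group. List lengths ran from 2893 to 12419 in Chow and from 10143 to 23582 in FFC, and the 2 ranges overlap.

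Libraries of the same diet shared slightly more of their open chromatin than libraries of different diets, and the excess was not larger than other groupings of the 8 libraries gave. The mean Jaccard index, the shared base pairs over all base pairs covered by either list, was 0.413 within groups and 0.384 between groups (exact permutation test, one-sided, p = 0.143 over 35 splits). FFC pairs averaged 0.493 and Chow pairs 0.334, and the most similar pair of all, at 0.596, joined Chow replicate 4 with FFC replicate 1. Unequal list length limits this index. Chow replicate 1 and FFC replicate 4 had 0.0644, although 98.3% of the peaks of the shorter list overlapped the longer one. Averages of pairs therefore reflect list length as well. The within-group excess of 0.0294 turned to -0.00318 without FFC replicate 3 and to -0.00857 without FFC replicate 4. With any other single library left out it was 0.00448 to 0.103. At equal list length the excess was 0.0338 (exact permutation test, one-sided, p = 0.114). Taken as the share of the shorter list's peaks that overlap the other list, it was 0.0156 (exact permutation test, one-sided, p = 0.0857).

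Merging all peaks gave 24825 regions, of which 2552 had a peak in all 8 libraries. Regions with a peak in every FFC library and in no Chow library numbered 197, against 1 region with the opposite pattern. Among the 197, regions lay inside Sele, which encodes the endothelial adhesion receptor E-selectin (chromosome 1, 164043594 to 164043967), and at an end of Cd40, a co-stimulatory receptor (chromosome 2, 165055336 to 165055752). A region at an end of H2-Aa, an MHC class II chain, spanned 34287792 to 34287991 on chromosome 17, and another lay 2292 bp outside Tap2, a peptide transporter of MHC class I loading (chromosome 17, 34218613 to 34219054). Others lay inside Bcl3, a regulator of NF-kB, inside Maff, a small Maf transcription factor, inside Abca1, a cholesterol exporter, 5211 bp outside the endothelial receptor gene Tie1 and 7740 bp outside the endothelial transcription factor gene Ets2. These 9 were singled out after their values were seen, as the FFC-only regions within 10 kb of a gene of the 24 fixed lists. Of the 197 regions, 37.1% lay within 1 kb of a gene end, 29.9% elsewhere in gene bodies and 33.0% between genes. The single Chow-only region lay on chromosome 3, 8245314 to 8245479, 264048 bp from the nearest protein-coding gene, Stmn2.

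No region passed Fisher's exact test after Benjamini-Hochberg adjustment over 24825 regions, where 198 had an unadjusted p of 0.0286, the smallest that 4 against 4 libraries allow. With that limit no region could pass unless most regions reached the smallest p, so this outcome does not show that regions were alike. The count of FFC-only regions was 10 with lists of equal length, where the Chow-only count was 11. A criterion with 1 library fewer is looser by construction, and the count was 349 without Chow replicate 3, 580 without Chow replicate 4, 346 without FFC replicate 1 and 708 without FFC replicate 2.

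A test that gives each library its own odds of a peak, and so takes list length into account, called 1 of 22273 regions, the Chow-only region near Stmn2 (exact conditional p = 2.89e-07, adjusted p = 0.00644). The next regions by p were also higher in Chow. They lay 8377 bp outside P4ha2 on chromosome 11 (54140045 to 54140223), a collagen prolyl hydroxylase gene, and inside Litaf on chromosome 16 (10975043 to 10975239). Each had a peak in 4 Chow libraries and 1 FFC library (exact conditional p = 2.68e-05, adjusted p = 0.199). Another region inside Litaf (10976118 to 10976601) had the opposite lean, with a peak in 4 FFC and 0 Chow libraries, so Litaf as a whole did not lean to Chow. Regions nearest Slc16a14 (chromosome 1, 84993344 to 84993481) and inside Gm38510 (chromosome 1, 85185532 to 85185738) had peaks in 3 Chow and 0 FFC libraries (exact conditional p = 0.000118, adjusted p = 0.328). Both were the first by position of 5 regions tied at these counts. Toward FFC, the first regions by position were nearest Ccdc115, Rnf149, Il1r2, Sgo2a and Klf7, each with a peak in 4 FFC and 0 Chow libraries (exact conditional p = 0.0829, adjusted p = 1.0). Since 0.0829 is the smallest p this test can give any region higher in FFC here, it could not call any of the 197. At an unadjusted p under 0.05 it listed 600 regions, which by that limit could only be higher in Chow. Of these 600 regions, 425 had a peak in just 1 Chow library and in 0 FFC libraries, so most were not shared among Chow libraries. The Stmn2 region is 1 region only, and the count was 0 without Chow replicate 1, Chow replicate 2 or FFC replicate 4, and 2, 4 and 3 without Chow replicate 3, Chow replicate 4 and FFC replicate 1. Of the 35 splits of the 8 libraries into 4 and 4, 5 gave as many calls, so the call is not particular to diet. Known artefact regions were not removed, and whether the called region is one was not tested.

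At the gene level, 10352 of 21887 protein-coding genes had a gene-end peak in at least 1 library and 2307 had one in all 8. Several endothelial genes chosen in advance had gene-end peaks in both groups. Stab1, a scavenger receptor of LSECs, had a gene-end peak in 3 Chow and 3 FFC libraries, Kdr (VEGF receptor 2) in 3 and 4, and Nos3 (endothelial nitric oxide synthase) in 3 and 3. Lyve1, a hyaluronan receptor of LSECs, had one in 1 Chow and 4 FFC libraries, Cdh5 (VE-cadherin) in 1 and 3, Pecam1 in 1 and 1, and Stab2 in 0 and 1. Icam1, a leukocyte adhesion receptor, had a gene-end peak in 0 Chow and 3 FFC libraries, and Cd34, a marker of continuous endothelium, also in 0 and 3. Vcam1 had one in FFC replicate 4 alone. Cd36 had no gene-end peak and 1 peak within 10 kb, in FFC replicate 4. Clec4f (Kupffer cells), Alb (hepatocytes), Lrat (stellate cells) and Cd3e (T cells) had no peak within 10 kb in any library. Other markers of such cells did have peaks. Cd3d, of the T and NK cell list, had a gene-end peak in 0 Chow and 3 FFC libraries, and Trf, of the hepatocyte list, in 1 and 4. Actb had no gene-end peak, but 3 Chow and 4 FFC libraries had a peak within 10 kb.

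Of the list genes, 18 differed by 3 or 4 libraries, and all 18 were found in more FFC libraries. This direction was not particular to the list genes, since 643 of all protein-coding genes differed by 3 or 4 libraries toward FFC and 0 toward Chow. Cd40 and H2-Aa had a gene-end peak in 4 FFC and 0 Chow libraries. Bub1, Cd34, Cd3d, Cxcl1, Cxcl9, Icam1, Ikbkb and Lrp1 had one in 3 FFC and 0 Chow libraries. Cxcl10, Il1a, Jam2, Keap1, Lyve1, Nlrc5, Top2a and Trf had one in 4 FFC and 1 Chow library. They include the interferon-induced chemokines Cxcl9 and Cxcl10, the neutrophil chemokine Cxcl1, and Nlrc5, the transactivator of MHC class I genes. Markers of other cell types are among them too, namely Cd3d of the T and NK cell list and Trf of the hepatocyte list. Across all genes, 68 had a gene-end peak in 4 FFC and 0 Chow libraries and 0 had the opposite. The first 10 of these by name were Acaca, Arhgap45, Arsg, Cd40, Ckap5, Dusp16, Eri2, Ext2, Fam193b and Fmn1. None passed adjustment over all genes (Fisher's exact test, two-sided, p = 0.0286 for 4 against 0, adjusted p = 1.0). None could have passed unless most genes reached that smallest p. In the list-length-adjusted test 0 of 8045 genes passed, and 100 had an unadjusted p under 0.05. These could only be higher in Chow, since 0.088 is the smallest p that test can give a gene higher in FFC. All 40 named genes lacked a gene-end peak in every list of the best 2893 peaks, so that setting could not compare them. FFC replicate 2, the shortest FFC list, lacked the peaks at Bub1, Cd34, Cd3d, Cxcl1, Cxcl9, Icam1 and Ikbkb.

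**Figure D2:**
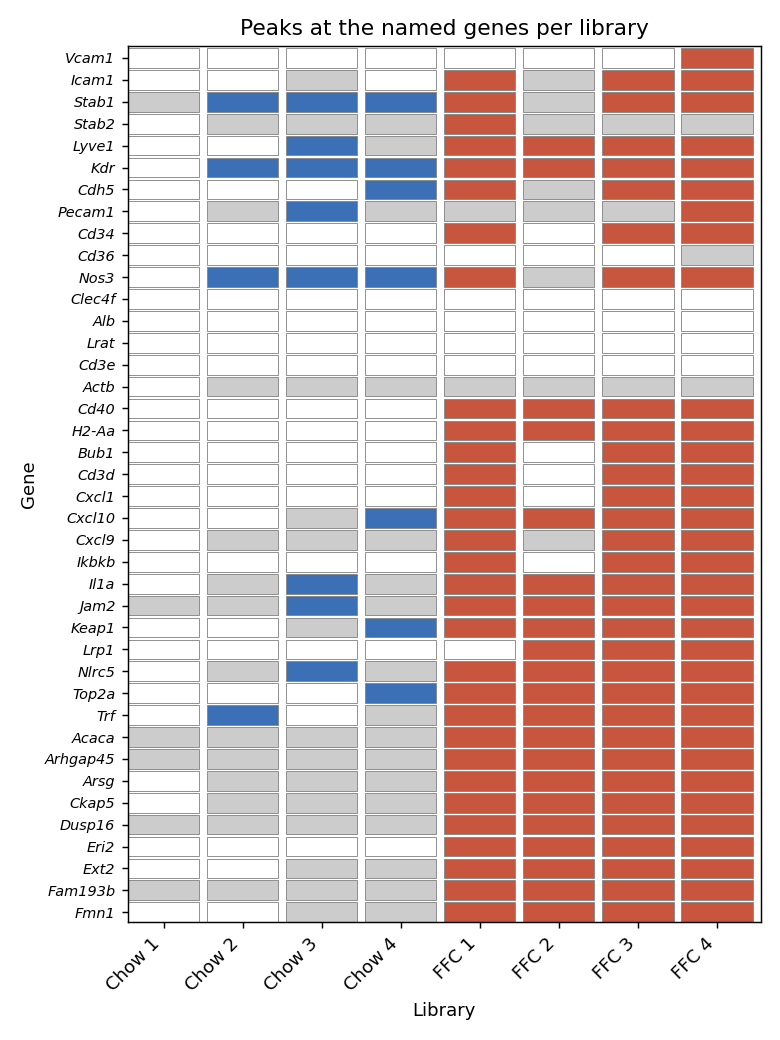
Peaks at the 40 named genes (rows) in the 8 libraries (columns): coloured cells have a peak within 1 kb of a gene end (blue Chow, red FFC), grey cells have a peak within 10 kb of the gene only, and white cells have none. Cd40 and H2-Aa are coloured in 4 FFC and 0 Chow libraries, while Clec4f, Alb, Lrat and Cd3e are white throughout. Cd3d, of the T and NK cell list, is coloured in 3 FFC and 0 Chow libraries, and Trf, of the hepatocyte list, in 4 and 1.

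**Figure D3:**
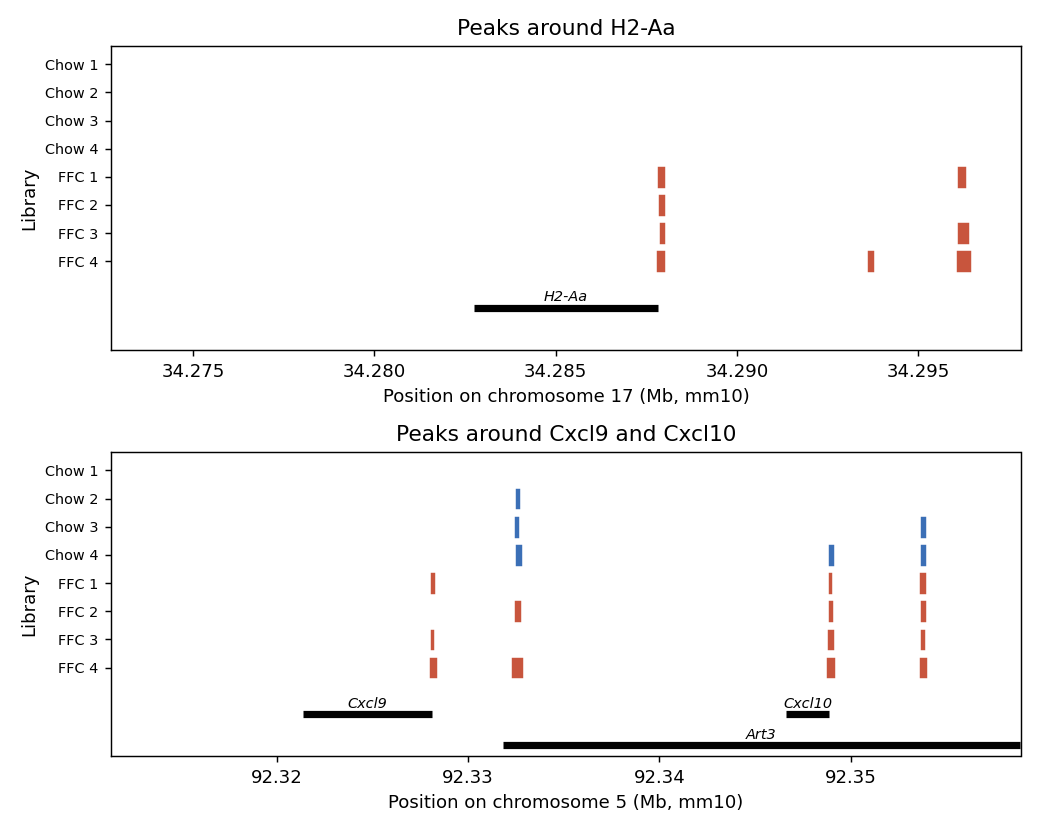
Peaks (blocks) of each library around H2-Aa on chromosome 17 (top) and around Cxcl9 and Cxcl10 on chromosome 5 (bottom), in Mb of mm10; black bars are genes, blue blocks Chow and red blocks FFC. At H2-Aa all peaks belong to the 4 FFC libraries, while at Cxcl10 1 Chow library also has a gene-end peak.

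On the log2 odds scale, leukocyte adhesion and chemokines and cytokines differed most toward FFC of the 24 gene lists; in percent of genes, antigen presentation differed most. In the leukocyte adhesion list, 14.3% ± 10.1 (SD, n = 4) of 14 genes had a gene-end peak in Chow and 41.1% ± 17.9 (SD, n = 4) in FFC. In the chemokine and cytokine list the shares of 18 genes were 16.7% ± 12.0 (SD, n = 4) and 41.7% ± 14.0 (SD, n = 4). Taken as log2 odds against each library's other genes, the differences were 1.19 for adhesion and 1.17 for chemokines, and every FFC library lay above every Chow library (exact permutation p = 0.0286, adjusted p = 0.343 over 24 lists). Chow replicate 1 had a gene-end peak at 0 genes of either list, so its values rest on the 0.5 added to each cell. Of the adhesion genes, 9 had a peak in more FFC than Chow libraries, 0 in more Chow libraries and 5 were equal, with Icam1 and Jam2 differing most. Of the chemokine genes, 9 leaned to FFC, 0 to Chow and 9 were equal, with Cxcl1, Cxcl9, Cxcl10 and Il1a differing most. Such counts were not particular to these lists. Of the ubiquitous control genes 10 leaned to FFC and 0 to Chow, and of the lipid handling genes 12 and 0. No list had more than 2 genes leaning to Chow. At 2893 peaks per list the differences were 0.30 for adhesion and for chemokines (exact permutation p = 1.0 for each), and with the better part of each list they were 0.15 and -0.050 (exact permutation p = 0.686 and 0.943). Without Chow replicate 1, 2, 3 or 4 the adhesion difference was 0.94, 1.28, 1.30 or 1.23, each with an exact permutation p of 0.0571, and the chemokine difference was 0.78 without Chow replicate 1 and 0.95 without FFC replicate 4, also with 0.0571. When the 6 longest lists were compared at 10143 peaks each, the differences were 0.37 for adhesion, -0.00386 for chemokines and 0.73 for antigen presentation (exact permutation p = 0.4, 1.0 and 0.2).

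The antigen presentation list had gene-end peaks at 36.8% ± 13.0 (SD, n = 4) of 17 genes in Chow and 64.7% ± 11.8 (SD, n = 4) in FFC, a log2 odds difference of 0.73 (exact permutation p = 0.0571, adjusted p = 0.457). Of its genes 11 leaned to FFC and 0 to Chow, a one-sided count that was not particular to this list. The NF-kB list had 52.8% ± 24.6 (SD, n = 4) and 75% ± 17.3 (SD, n = 4) (difference 0.54, exact permutation p = 0.343, adjusted p = 0.686), and the interferon list 37.5% ± 20.4 (SD, n = 4) and 62.5% ± 18.4 (SD, n = 4) (difference 0.64, exact permutation p = 0.229, adjusted p = 0.686). Cell cycle genes, among them Top2a and Bub1, had a difference of 0.84 (exact permutation p = 0.0857, adjusted p = 0.514). LSEC identity genes had gene-end peaks at 42.5% ± 22.5 (SD, n = 4) in Chow and 53.8% ± 16.5 (SD, n = 4) in FFC, with 8 of 20 genes leaning to FFC, 2 to Chow and 10 equal. Against each library's other genes, the log2 odds differences were -0.13 for LSEC identity (exact permutation p = 0.743), 0.43 for pan-endothelial genes (p = 0.657, exact permutation) and 0.79 for capillarization and continuous endothelium (p = 0.314, exact permutation). With lists of equal length the LSEC identity difference was -1.91 (exact permutation p = 0.0286), which rests on 2 to 3 genes per Chow library and 0 to 1 per FFC library, and with the 6 longest lists at equal length it was -0.02 (exact permutation p = 0.933). The other differences were -0.00018 for MAPK and AP-1, 0.44 for angiocrine and BMP signals, 0.16 for nitric oxide and flow response, -0.11 for TGF-beta and matrix, 0.57 for lipid handling, 0.46 for stress and unfolded protein response and 0.35 for the ubiquitous control genes, with exact permutation p from 0.143 to 1.0. No list passed after adjustment, 2 of 24 had an unadjusted p under 0.05, and 0 genes of any list passed when adjusted over the list alone. By Fisher's exact test a gene could pass there only if most genes of its list had a peak in all libraries of one group and none of the other. The lack of passing genes therefore decides nothing.

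**Figure D4:**
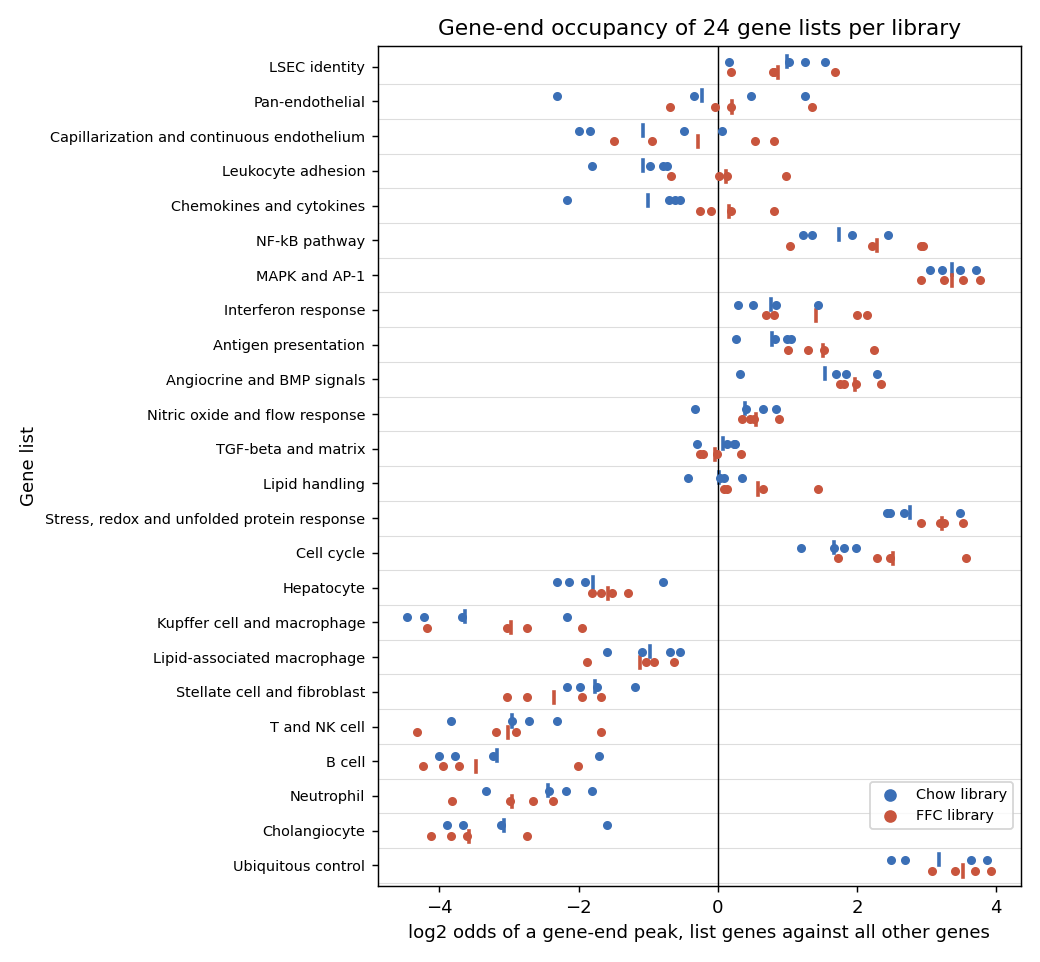
Log2 odds of a gene-end peak for the genes of each of 24 lists against all other genes (horizontal axis), per library; blue points are Chow libraries, red points FFC libraries, and the short bars are group means. For leukocyte adhesion and for chemokines and cytokines, all 4 FFC points lie to the right of all 4 Chow points, with an adjusted p of 0.343 for each.

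Most markers of the other liver cell types had no gene-end peak in any library. A missing peak does not show closed chromatin, since Actb lacked one as well. Gene-end peaks were found at 0.0% of the Kupffer cell and macrophage list in Chow and 6.94% ± 6.99 (SD, n = 4) in FFC, at 2.5% ± 2.89 (SD, n = 4) and 7.5% ± 8.66 (SD, n = 4) of the T and NK cell list, and at 0.0% and 3.85% ± 7.69 (SD, n = 4) of the B cell list. The neutrophil list had 3.57% ± 4.12 (SD, n = 4) and 5.36% ± 3.57 (SD, n = 4), the hepatocyte list 8.75% ± 6.29 (SD, n = 4) and 16.2% ± 2.5 (SD, n = 4), and the stellate cell and fibroblast list 8.33% ± 5.56 (SD, n = 4) and 9.72% ± 5.32 (SD, n = 4). The lipid-associated macrophage list had 14.6% ± 10.5 (SD, n = 4) and 20.8% ± 4.81 (SD, n = 4), and the cholangiocyte list 0.0% and 2.08% ± 4.17 (SD, n = 4). Their log2 odds differences ran from -0.58 (stellate cell and fibroblast) to 0.66 (Kupffer cell and macrophage), and the smallest exact permutation p was 0.257 (adjusted p = 0.686). Where a library had 0 genes of a list, its log2 odds rest on the 0.5 added to each cell.

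Distal peaks were those not within 1 kb of an end of any protein-coding gene, and antigen presentation loci held them in FFC libraries only. Within 10 kb of the antigen presentation genes there were 0 such peaks in each Chow library and 2, 1, 3 and 11 in FFC replicates 1 to 4, which was 0.0491% ± 0.0231 (SD, n = 4) of the distal peaks of the FFC libraries (exact permutation p = 0.0286, adjusted p = 0.263 over 23 lists). Peaks near ends of neighbouring genes are left out by this definition. Chow replicates 2 and 4 each had 1 peak within 10 kb of Nlrc5 that was not at an end of Nlrc5 itself. Loci of the ubiquitous control genes held 0.148% ± 0.0387 (SD, n = 4) of distal peaks in Chow and 0.0881% ± 0.028 (SD, n = 4) in FFC (exact permutation p = 0.0286, adjusted p = 0.263). This second direction turned at equal list length, where the difference was 0.193 percentage points. Chemokine and cytokine loci held 0.0412% ± 0.0342 (SD, n = 4) and 0.105% ± 0.0235 (SD, n = 4), and lipid handling loci 0.143% ± 0.022 (SD, n = 4) and 0.202% ± 0.0443 (SD, n = 4) (exact permutation p = 0.0571 and adjusted p = 0.263 for each). Markers of other cell types stood beside them: hepatocyte loci held 0.00524% ± 0.0105 (SD, n = 4) in Chow and 0.0285% ± 0.0104 (SD, n = 4) in FFC (exact permutation p = 0.0571, adjusted p = 0.263), and lipid-associated macrophage loci 0.0102% ± 0.0118 (SD, n = 4) and 0.0302% ± 0.011 (SD, n = 4) (exact permutation p = 0.0857, adjusted p = 0.329). LSEC identity loci held 0.428% ± 0.0711 (SD, n = 4) in Chow and 0.338% ± 0.0485 (SD, n = 4) in FFC (exact permutation p = 0.114, adjusted p = 0.329). No list passed after adjustment, and 2 of 23 had an unadjusted p under 0.05. At equal length no antigen presentation locus held a distal peak in any list, so that setting gave no value, and leaving out any 1 Chow library left the difference at 0.0491 percentage points with an exact permutation p of 0.0571. It was 0.0108 with the better part of each list and 0.028 with the 6 longest lists at equal length (exact permutation p = 1.0 and 0.333).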

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

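Among 110 groups of 4 library values, 5 held a library far from the other 3, close to the 1 in 20 that chance gives. In the chemokine and cytokine list, Chow replicate 1 had a log2 odds of -2.17 against -0.71 for the nearest Chow library. It had a gene-end peak at 0 of these genes, so its value rests on the 0.5 added to each cell. FFC replicate 1 had 0.819% of its distal peaks in pan-endothelial loci, and the nearest FFC library had 0.557%. Chow replicate 4 had 0.021% of its distal peaks, which was 1 peak, in hepatocyte loci, where the other Chow libraries had 0.0%. Chow replicate 1 had 0.0% in Kupffer cell and macrophage loci against 0.0398% for the nearest Chow library. Chow replicate 3 had 0.0199%, also 1 peak, in neutrophil loci, where the other Chow libraries had 0.0%.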

How the results depend on the processing

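The settings that left out the shortest and longest list, that compared the 6 longest lists at equal length, and that used fitted library odds were chosen after seeing the data. At equal length (2893 peaks) the gene-end share was 4.45 percentage points higher in FFC, and there were 10 FFC-only, 11 Chow-only and 0 length-adjusted regions. In that setting 3 list values were reversed: ubiquitous control gene ends at -0.19 and cell cycle and ubiquitous control loci at 0.119 and 0.193. With the better part of each list there were 92 FFC-only, 0 Chow-only and 0 length-adjusted regions, and the chemokine difference was -0.050. With occupancy in at least 3 libraries of one group the counts were 935 and 6, looser by construction. Leaving out the shortest and longest list gave 208 FFC-only, 24 Chow-only and 0 length-adjusted regions, with both counts looser by construction at 3 against 3 libraries. The 6 longest lists at equal length gave a gene-end share 2.07 points higher in FFC and a chemokine difference of -0.00386. In that setting there were 147 FFC-only regions, 159 Chow-only regions (2 Chow libraries by construction) and 0 length-adjusted regions. Leaving out 1 library at a time gave 201 to 708 FFC-only regions, 1 to 4 Chow-only regions, 0 to 4 length-adjusted regions, and a within-group excess of overlap of -0.00857 to 0.103, which was -0.00318 without FFC replicate 3. Apart from what the construction explains, the cause was not tested. The log2 difference in peak number was 0.49 to 1.19 with 1 library left out and 0.27 without the shortest and longest list, short of the threshold in each setting run. The number of lists passing adjustment was 0 in every setting run, a design that could hardly pass any. Of 366 gene-end and 313 locus values of lists under other settings, 338 and 290 kept their side of the unadjusted threshold, though differences that missed it changed sign in some settings, and pairing by number, 3 against 3 libraries and the 6 longest lists cannot reach 0.05 by design, so there it says nothing about stability. Of 560 values of named genes, 73 moved and 0 were reversed. Only genes that differed by at least 3 libraries could count as reversed. Leaving out 1 library cannot turn the sign of such a gene, and at 2893 peaks no named gene had a gene-end peak. The lack of reversals therefore says little about stability.

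Replicate numbers did not pair the libraries: the correlations of same-numbered libraries were -0.299, 0.108, 0.0234 and -0.339, and Chow replicate 2 alone correlated best with its own number. With the replicate block, 0 length-adjusted regions were called against 1 without it, and the sign-flip p of the log2 peak number was 0.125, the smallest 4 pairs allow. The motif and GC comparisons and their alternatives were not run, since no genome sequence was used. Cholangiocyte loci held no distal peak and gave no value, and at equal length lists without a distal peak in any library, antigen presentation among them, gave none either. Read depth is unknown, so a missing peak can reflect depth.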

Other observations

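The tests of list length, nearby genes, other cell types and splits below were chosen after the results were seen, except the splits for genes. Some FFC-only regions lay near antigen presentation genes. Of the 197 FFC-only regions, 3 (1.52%) were within 10 kb of an antigen presentation gene, namely Tap2, H2-Aa and Cd40, against 0 of 1395 other regions with a peak in exactly 4 libraries (Fisher's exact test over regions, p = 0.00187, adjusted p = 0.0449 over 24 lists). Regions are not replicates, 2 of these 3 are the gene-end peaks already described, and Tap2 and H2-Aa are both on chromosome 17 in the MHC, so the p adds no evidence beyond the gene-end counts. For the adhesion, chemokine and antigen presentation lists joined, 4 FFC-only regions (2.03%) were near their genes, of which 2 are those same gene-end peaks, so the share decides nothing about these lists. No other list passed adjustment, and 9 FFC-only regions (4.57%) against 49 others (3.51%) were near a gene of any list (Fisher's exact p = 0.419).

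FFC-only regions outnumbered Chow-only regions, 197 to 1. Of the 35 splits of the 8 libraries, 3 gave as many regions on 1 side, and the highest other, 406, came from the 4 longest lists (Chow replicate 4 with FFC replicates 1, 3 and 4), so chance cannot be excluded. The same was true of genes, where 4 splits gave 68 or more and those 4 lists gave 217, and of the 1 region called with list length taken into account, where 5 splits gave as many and the highest other gave 1. Longer FFC lists remain a candidate explanation: library odds alone predict 123.6 FFC-only regions, and the observed count was 1.59 times that. This was above the 1.4 of the next of 12 splits with expected counts of at least 26.3. Some splits with smaller expected counts had higher ratios. Chow replicates 2, 3 and 4 with FFC replicate 4 had 23 regions against 7.26 expected, a ratio of 3.17. At equal length of the 6 longest lists, 147 regions were in 4 FFC and neither Chow list, the most of 15 splits but close to the next, 122, so list length and diet cannot be told apart.

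The adhesion, chemokine and antigen presentation lists leaned to FFC. With occupancy taken relative to fitted library odds, the FFC excess was 0.0529 for adhesion and 0.0881 for antigen presentation (exact permutation p = 0.0286, the smallest possible; adjusted p = 0.171, which could pass only if most lists reached that p) and 0.0346 for chemokines (exact permutation p = 0.314, adjusted p = 0.686), but these lists were picked for their lean, so list length stays open. On that measure the lean was not shared by all immune lists nor limited to them: NF-kB was at -0.023 and interferon at 0.0105 (exact permutation p = 0.657 and 0.83), and cell cycle at 0.0373 (exact permutation p = 0.0286, adjusted p = 0.171). At equal length of the 6 longest lists, FFC libraries averaged 3.5 more of the 49 genes than Chow libraries, with FFC replicate 3 matching Chow replicate 4 at 13, and the log2 odds difference of antigen presentation was 0.73 (exact permutation p = 0.2 over 15 assignments). Leukocytes passing the CD146 selection may also contribute: 4 joined leukocyte lists did not lean to FFC (-0.00498, exact permutation p = 0.514), but 54 of their 65 genes had no gene-end peak in any library, so this cannot be told apart, and an effect of diet on the endothelium also stays open as untested.

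The LSEC identity list was lower in FFC relative to list length, by -0.126 in mean occupancy (exact permutation p = 0.0286, adjusted p = 0.171). With all lists at equal length the log2 odds difference was -1.91 (exact permutation p = 0.0286), but on 2 to 3 of 20 genes per Chow library and 0 to 1 per FFC library, which is too few to weigh, and it was higher in FFC with the better part of each list (0.36, exact permutation p = 0.571). At equal length of the 6 longest lists the FFC mean was 0.25 genes above the Chow mean, with FFC libraries on both sides of the Chow value of 9, so list length cannot be told apart as a candidate explanation. A lower endothelial share of the FFC samples cannot be told apart either. The pan-endothelial difference was -0.136 in mean occupancy relative to list length (exact permutation p = 0.143, adjusted p = 0.571). In log2 odds it was 0.43, higher in FFC (exact permutation p = 0.657), so its sign depended on the measure. An effect of diet on LSEC identity also stays open as untested.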
